A study of Mus musculus with 65 samples.

How the data were processed

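Primary neural stem cells (NSCs) were taken, per the labels, from the subventricular zone of adult mice carrying a doxycycline-inducible cassette for Oct4, Sox2, Klf4 and Myc (OSKM), and their poly(A) RNA was sequenced. The labels give 65 libraries in 15 groups from 5 young mice (3 to 4 months) and 4 old mice (25 months) of both sexes. Libraries from stem cell medium, which contains EGF and bFGF, are called NSC here. Libraries from cells moved 18 h after plating to medium without these factors are called differentiation libraries. Doxycycline was used at 2 µg per ml. Young animals gave untreated libraries at 18 h in stem cell medium and at 6, 18 and 48 h of differentiation, and doxycycline libraries at 18 h in stem cell medium. Old animals gave the same groups, doxycycline libraries at 6 and 48 h in stem cell medium, and doxycycline libraries at each time of differentiation. The labels list no untreated stem cell medium group at 6 or 48 h.

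Per the labels' protocols, libraries were made with a stranded poly(A) kit, pooled, and sequenced together as paired reads. The submitters' processing notes name Trim Galore 0.6.6, STAR 2.7.10b, SAMtools, Subread and DESeq2 1.40.1 with mouse build mm10, without their settings. The deposited count table holds integer counts for 31057 features and 65 libraries and is not normalised or filtered beyond what the counting did. Most of its smallest values are even (75644 values of 2 against 19963 of 1), so both mates of most read pairs were counted and a fragment usually adds 2 counts. The authors also deposited variance-stabilised values on a log2 scale, computed with DESeq2 per the submitters' processing notes, which served as an alternative data source; for genes above a mean of 5000 counts these differed from log2 scaled counts by a median of 0.08. Of the features, 30934 were named from the GENCODE M21 annotation of the same build, 123 had no match, and 4 are transgene sequences.

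Totals ran from 56.5 M to 116.8 M counts per library (median 86.7 M). The precision of each change is given by its SE, which in the main fits holds the spread between animals as well as counting error. In fits that pair the libraries of an animal, described below, differences in level between animals are removed from it. Levels are given as CPM, counts scaled to a common library total. Levels of Xist and Ddx3y matched the labelled sex in all 65 libraries, and no 2 libraries were identical.

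Each comparison of 2 groups was fitted on the libraries of those groups alone with edgeR 4.0.16 (R 4.3.3): TMM normalisation, filterByExpr with a minimum count of 10, robust quasi-likelihood fits and Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. The 17 comparisons tested 16621 to 17797 genes together with 4 interactions, which ask whether an effect differed between ages. Differences are log2 fold changes with their standard errors (SE), and group levels are TMM-scaled CPM with standard deviations (SD). The tests, the samples, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Adjusted p-values given for genes and lists come from edgeR and limma; p-values for single measures come from exact two-sided permutation tests, whose smallest possible value is 0.0286 for 4 against 4 libraries and 0.00794 for 5 against 5. Exact p-values for the factors were adjusted over 20 matched tests.

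Within an age, the replicate number and the animal number in the labels name the same animal, so the libraries of one age are paired. The values bear this out: in the 13 comparisons within an age, deviations from the group means over 11822 genes correlated between libraries of the same animal by medians of 0.51 to 0.83 (lowest single pair 0.28), against medians of -0.28 or lower between different animals, and 54 of 56 libraries lay closest to their own animal. The main design has no animal term, because the labels state no model. The fit with animals as blocks was fixed as an alternative, and its values are given where they change a call or a count by more than 1.5 times. For comparisons of age, sex was the alternative covariate.

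Gene lists (31 lists, 584 symbols, 1 without a feature in the table) were written down from general knowledge. Each was tested in every comparison with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 651 list tests, 191 passed with the preset correlation and 6 with an estimated correlation, so list results with preset values alone are weak evidence. Counts of list members that passed are given over all genes and, where they differ, adjusted over the list alone. The ribosome biogenesis list also holds MYC targets. A symbol shared by several features counts once for each feature, as Ddit3 does among integrated stress response genes. Genes are named by a rule: up to 6 genes per direction with the largest fold change among called genes with a mean of at least 5 CPM and non-overlapping groups, skipping unnamed models; up to 4 members with the smallest adjusted p of each list described; the 4 factors in each comparison with doxycycline; and up to 6 genes per direction with the smallest adjusted p for interactions and for genes moved back. Not every gene that meets the rule is printed. In fits with animals as blocks the same rule was applied with the same direction in each animal in place of non-overlapping groups, a change made after the data were seen.

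A gene changed with age was counted as moved back when doxycycline shifted it in the opposite direction in old cells. Both comparisons share the untreated old libraries, which alone makes changes look opposed. The share was therefore set beside 5 simulations with the observed age effects and no doxycycline effect. It was also recomputed over 6 splits in which the age and doxycycline comparisons used different untreated animals. The splits had animals as blocks for doxycycline and age genes taken at an unadjusted p under 0.01. The simulations keep the shared libraries and so serve as a reference for the full data. They take each untreated old library as the true level of its animal, so noise already in it counts as an age effect. New spread is drawn for each gene on its own, without shifts common to many genes of a library. Their range is therefore not a test of the share. The splits share no library between the comparisons. Without a doxycycline effect both directions would be equally likely there only if the untreated old libraries have no state in common. That group enters both comparisons of every split with opposite signs, so such a state would also raise the share.

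The fits were tested on simulated counts for the real genes, with 200 genes of at least 5 CPM changed by known folds. For doxycycline, the spread within an animal was set to the same fixed value for every gene rather than estimated. The doxycycline shares below therefore need not hold for the real data. There the blocked fit of old cells at 18 h called genes at a median absolute log2 fold change of 0.131. For doxycycline in old cells at 18 h, the unblocked fit recovered 3% of genes changed 1.2-fold, 82.1% of those changed 1.5-fold and 100% of those changed 3-fold, and the blocked fit 22.4%, 100% and 100%. For age in stem cell medium the same figures were 38.8%, 95.5% and 100%, and for the interaction at 48 h 16.4%, 86.6% and 98.5%. At most 8.2% of edgeR calls in these simulations were false. DESeq2 1.42.0, run as an alternative, gave 19.2% false calls in the simulated age comparison.

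Alternatives changed the filter, the normalisation, the count model, the data source, the libraries entering the fit and the covariates, and left out each animal in turn. Others were chosen after seeing the data: counts halved, the share of counts on features overlapping ribosomal RNA as a covariate, corrections for GC content and gene length, doxycycline libraries at 18 h as the control for those at 6 and 48 h, and the alternatives run on blocked fits. No library was left out of the main fits. Counts on features that overlap one another, on mitochondrial genes with near-identical nuclear copies, and on symbols shared by 2 features can be split between features and are uncertain.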

Results

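Neural stem cells from 5 young and 4 old mice were read out by poly(A) RNA sequencing with and without induction of OSKM, in stem cell medium and after 6, 18 and 48 h of differentiation. Group dominated the variation. The first principal component over 500 genes held 78.0% of the variance and the group accounted for 99.8% of its spread, while the third component (5.9%) followed sex (98.7%) and animal (99.5%). Differentiation libraries differed from stem cell medium in most tested genes, age changed 246 to 1815, and doxycycline changed 2 to 6 genes per matched comparison, or 150 to 2260 with animals as blocks.

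Oct4, encoded by Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772), is the pluripotency factor of the cassette that adult neural stem cells do not need, so its transcript reads the induction most directly. At 18 h in stem cell medium Pou5f1 lay at 0.404 ± 0.131 CPM with doxycycline and 0.161 ± 0.0591 CPM without it in old cells (mean ± SD, n = 4 and 4, 2.52 times, exact two-sided p = 0.0571). In young cells it lay at 0.791 ± 0.356 against 0.207 ± 0.136 CPM (n = 5 and 5, 3.83 times, exact p = 0.00794). In old differentiation libraries the ratios were 5.25 at 6 h (exact p = 0.0286), 2.16 at 18 h (exact p = 0.0286) and 1.81 at 48 h (exact p = 0.0571). After adjustment over 20 matched tests none of these passed, the smallest adjusted value being 0.143. With so few libraries the smallest possible exact p-values are 0.0286 and 0.00794. The Pou5f1 tests could therefore not pass this adjustment on their own, whatever the levels. They also do not use the pairing of libraries by animal. Pou5f1 was higher with doxycycline than in the untreated library of the same animal in all 21 matched pairs, a count made after the data were seen. In edgeR fits with animals as blocks it passed at 18 h in stem cell medium in old (adjusted p = 0.0122) and young cells (adjusted p = 1.69e-04) and at 6 h of differentiation (adjusted p = 0.00494). It did not pass at 18 and 48 h of differentiation (adjusted p = 0.27 and 0.255), nor in any matched fit without blocks. These are levels near the floor of detection, and the table cannot separate cassette from endogenous reads of the 4 factors. Sox2, a stem cell factor with a high endogenous level, was at 256 against 260 CPM in old and 254 CPM in young cells with doxycycline, 1.01 times the level without it. Klf4 was at 8.62 against 8.17 CPM in old and 7.16 against 6.36 CPM in young cells. Myc, which drives growth and ribosome production, was at 161 ± 5.94 against 176 ± 5.43 CPM in old cells (exact p = 0.0286, adjusted 0.143) and 167 against 168 CPM in young cells. The sequence of the doxycycline-responsive activator M2rtTA was present in all 65 libraries at 81.7 to 283 CPM. The other transgene features, P2A, T2A and E2A, held at most 4 counts in any library, with or without doxycycline.

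**Figure D1:**
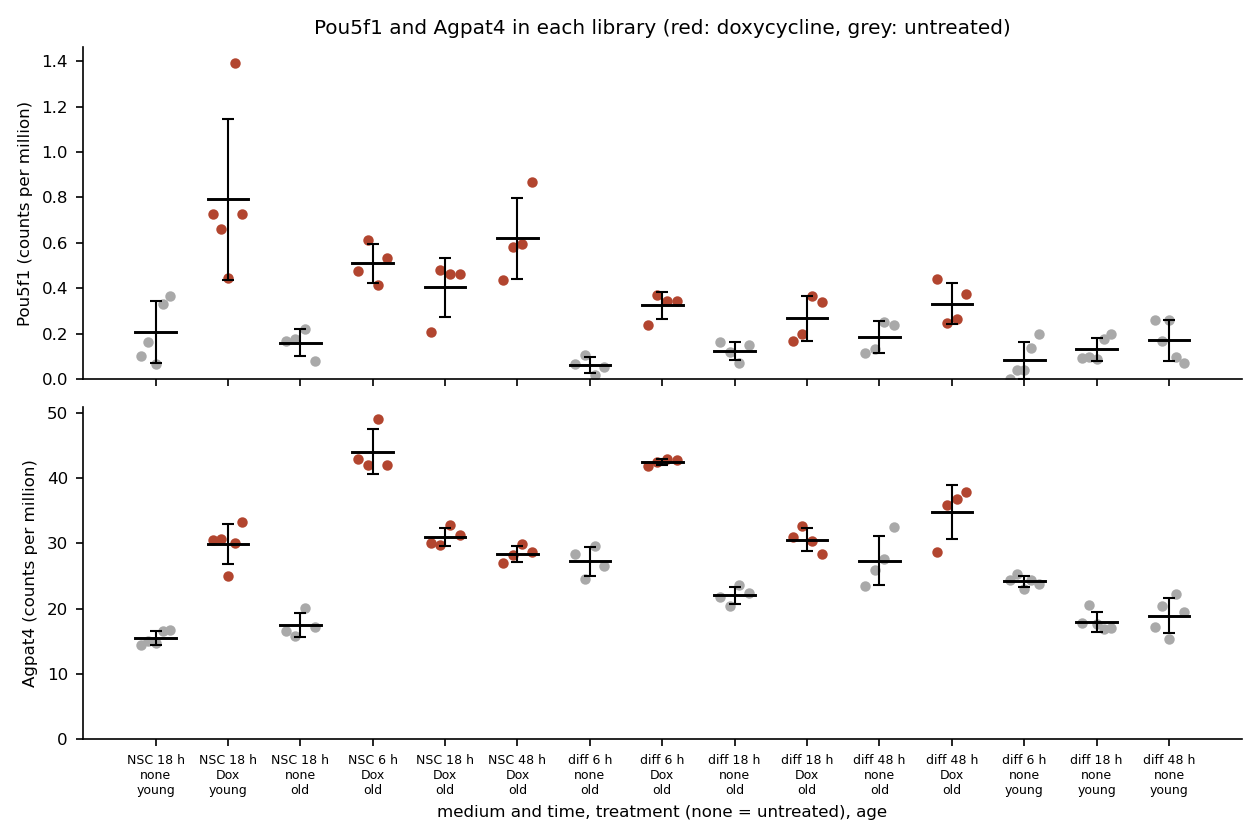
CPM (scaled counts) of Pou5f1 and Agpat4 in every library of the 15 groups, with group means and SD, doxycycline in red and untreated in grey. Agpat4 lies at 31.0 with doxycycline and 17.5 without it in old cells at 18 h.

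In old cells at 18 h in stem cell medium, doxycycline raised Agpat4 and Slc29a3 and lowered Ednrb. Agpat4 (ENSMUSG00000023827, chromosome 17, 12118704 to 12219645), an acyltransferase of phospholipid synthesis, rose from 17.5 ± 1.86 to 31.0 ± 1.38 CPM (log2 fold change 0.84 ± 0.07 SE, n = 4 and 4, adjusted p = 0.00281). Slc29a3 (ENSMUSG00000020100, chromosome 10, 60712072 to 60752794), a lysosomal nucleoside transporter, rose by 0.50 ± 0.06 (adjusted p = 0.0449), and the endothelin receptor gene Ednrb, an astrocyte and progenitor gene, fell by 0.27 ± 0.03 (adjusted p = 0.0449). Leaving out any 1 of the 8 libraries gave 1 to 2 called genes in place of 3, so at least 1 of the calls above was lost each time. Fewer libraries also lower the power of these fits, so the losses do not single out a library. Unadjusted p was under 0.05 for 1466 of 16652 genes. With animals as blocks 696 genes rose and 1167 fell. Among the largest of these, the sorting receptor gene Sorl1 rose by 0.64 (18.1 against 11.8 CPM), the signalling regulator Rgs8 by 0.52 and the adhesion gene Opcml by 0.50. The carbonic anhydrase gene Car3 fell by 0.63 (5.97 against 9.40 CPM), the kinase gene Stk32b by 0.51 and the water channel gene Aqp4 by 0.49 (7.66 against 10.8 CPM). Smaller falls were those of the GABA receptor gene Gabra4 by 0.48, the scavenger receptor gene Stab1 by 0.43 and the sialyltransferase gene St6galnac5 by 0.41. The mitochondrial transcript mt-Nd3 rose by 0.61 (199 against 131 CPM). Features overlapping ribosomal RNA took 1.71 ± 0.149% of counts with doxycycline and 0.981 ± 0.464% without it (exact p = 0.0286, adjusted 0.121), and with this share as a covariate the blocked fit called 731 genes.

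Agpat4 and Slc29a3 also rose in young cells at 18 h. Agpat4 rose from 15.5 ± 1.04 to 29.9 ± 3.01 CPM (0.95 ± 0.07, n = 5 and 5, adjusted p = 1.32e-04) and Slc29a3 by 0.64 ± 0.05 (adjusted p = 1.40e-04). Opcml rose by 0.67 ± 0.08 (adjusted p = 0.00285) and Sorl1 by 0.57 ± 0.06 (adjusted p = 0.00247). The taurine transporter gene Slc6a6 rose by 0.38 ± 0.05 (adjusted p = 0.0128) and the actin-binding gene Twf2 by 0.24 ± 0.03 (adjusted p = 0.0191). No gene fell (edgeR; 2403 genes had an unadjusted p under 0.05 in either direction, and DESeq2 called 213 genes in all). With animals as blocks 1139 rose and 1121 fell. The metalloprotease gene Adamts9 rose by 0.57 (51.7 against 34.8 CPM). Genes that fell include Car3 (-0.61), the kinase regulator Mob3b (-0.53), the nuclease gene Ankle1 (-0.51), the spindle gene Aspm (-0.47), the nuclear receptor gene Nr5a2 (-0.46) and the kinesin gene Kif14 (-0.43). Between the ages, which share no library, 175 genes rose in both blocked fits (48.1 expected) and 368 fell in both (79.6 expected), against 46 in opposite directions (128.2 expected). The interaction of doxycycline with age called 0 genes by edgeR (1516 with an unadjusted p under 0.05), 3 by DESeq2, and 589 with animals as blocks.

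Most cell cycle genes were called lower with doxycycline in 3 of the 5 matched comparisons when animals were blocks. In old cells at 18 h 34 of 37 tested members fell, led by the spindle assembly factor Tpx2 (-0.28 ± 0.02, 143 against 174 CPM), the mitotic transcription factor Foxm1 (-0.28), the chromatin protein gene Hmgb2 (-0.24) and the chromosomal passenger gene Cdca8 (-0.29). The list passed camera with the preset correlation (adjusted p = 4.67e-53) and fry (adjusted p = 0.0119), and had an adjusted p = 0.151 with an estimated correlation. In young cells 35 fell, led by the topoisomerase gene Top2a (-0.32 ± 0.03, 285 against 355 CPM), the checkpoint kinase gene Bub1b (-0.36), the nucleotide reductase subunit Rrm2 (-0.30) and the spindle gene Nusap1 (-0.35). The list had a camera adjusted p = 6.80e-62, a fry adjusted p = 0.0103 and an adjusted p = 0.237 with an estimated correlation. At 6 h of differentiation 26 members fell and 1 rose (29 and 1 adjusted over the list alone), led by Nusap1 (-0.24), Tpx2 (-0.22), Hmgb2 (-0.17) and the cyclin gene Ccna2 (-0.16). There it had a camera adjusted p = 3.94e-24 and an adjusted p = 0.346 with an estimated correlation. At 18 and 48 h of differentiation 1 of 37 was called lower at each time (medians -0.036 and -0.177). The list had a camera adjusted p = 0.124 and 3.78e-06, and an adjusted p = 0.528 and 0.138 with an estimated correlation. The median at 48 h lay below the -0.143 at 6 h, and a difference between the times was not tested.

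Other lists shifted with doxycycline in stem cell medium in the blocked fits. In old cells 12 of 23 tested quiescent stem cell and astrocyte markers fell (14 adjusted over the list alone; adjusted p = 0.151 with an estimated correlation), including the metallothionein gene Mt3 (-0.31), the glutamate transporter gene Slc1a3 (-0.14) and the glutamine synthetase gene Glul (-0.16). Of 32 extracellular matrix and adhesion genes 12 rose and 2 fell (adjusted p = 0.464 with an estimated correlation; 15 and 2 adjusted over the list alone). Col4a5 (0.23), Lamb1 (0.16) and Col4a1 (0.14) were up and the proteoglycan gene Ncan (-0.15) was down. The chaperone genes Hsp90b1 (-0.11), Hspa5 (-0.10), Pdia4 (-0.10) and Dnajb9 (-0.17) were among 7 of 15 unfolded protein response genes that fell (adjusted p = 0.464 with an estimated correlation). In young cells 12 of 25 glycolysis and hypoxia genes rose (20 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation), including Gapdh (0.27), Hk1 (0.22) and the collagen hydroxylase gene P4ha1 (0.20). Of 9 pluripotency network genes 1 fell in old and 1 in young cells (3 and 1 adjusted over the list alone, with 1 higher in each; camera adjusted p = 0.458 and 0.669).

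Old cells given doxycycline for 6 or 48 h in stem cell medium have no untreated group of their time, so both were set against untreated cells at 18 h and their differences join time with doxycycline. Against the 18 h doxycycline libraries, with doxycycline in both arms, 10222 genes differed at 6 h and 8814 at 48 h. These share 9135 (89.7%) and 7527 (85.3%) of the calls made against untreated cells, with 2 and 1 in opposite directions. At 6 h 5108 genes were higher and 5081 lower (61.3% of tested genes). The calcium-regulated transcription factor Nfatc2 was at 24.5 against 1.05 CPM (4.53 ± 0.21) and the synaptic ligand gene Nxph3 at 9.83 against 0.333 CPM (4.87 ± 0.32). The activin gene Inhba differed by 5.71, the Hippo pathway factor Tead4 by 4.19 ± 0.24 and the potassium channel gene Kcnk3 by 3.95 ± 0.24. St6galnac5 was at 1.12 against 17.6 CPM (-3.98 ± 0.14), the cholesterol exporter gene Abca1 at 4.27 against 58.2 CPM (-3.79 ± 0.26). The lactate transporter gene Slc16a3 (-3.75 ± 0.30), Crispld2 (-3.56 ± 0.24), Angptl2 (-3.18 ± 0.28) and Mybph (-2.89 ± 0.19) were also lower. All 22 cholesterol synthesis genes were higher (median 1.5, camera adjusted p = 1.29e-81, adjusted p = 0.00847 with an estimated correlation, 0.44 with animals as blocks). They were led by Idi1 (2.03 ± 0.04, 295 against 71.9 CPM), Msmo1 (1.96) and Hsd17b7 (1.88). Integrated stress response genes were higher in 17 of 22 cases, such as Atf3 (2.52) and Atf4 (1.15 ± 0.04, 469 against 210 CPM). Ribosome biogenesis genes and MYC targets were higher in 23 of 25 cases, such as Rrp12 (1.25) and Srm (0.86) (both lists: adjusted p = 0.332 with an estimated correlation). Of 13 Notch pathway genes 12 were lower, including Nrarp (-2.54), Notch3 (-1.80) and Hes1 (-0.92) (adjusted p = 0.0999 with an estimated correlation). Klf4 was at 18.7 ± 2.34 CPM, 2.29 times the untreated level at 18 h, and Pou5f1 at 0.510 ± 0.0846 CPM (3.17 times, exact p = 0.0286).

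At 48 h with doxycycline 4339 genes were higher and 4486 lower than in untreated cells at 18 h (52.5%). The oligodendrocyte precursor receptor gene Gpr17 (ENSMUSG00000052229, chromosome 18, 31942997 to 31949636) was at 26.1 against 3.08 CPM (3.10 ± 0.37). Mmd2 (3.05 ± 0.12), Itih5 (2.68 ± 0.11), Pla2g7 (2.61 ± 0.19), Als2cl (2.37 ± 0.15) and the glial calcium-binding gene S100b (2.12 ± 0.16, 18.4 against 4.32 CPM) were higher. Among the largest falls were those of Col6a2 (-4.81 ± 0.29, 0.899 against 25.5 CPM), the smooth muscle actin gene Acta2 (-4.26 ± 0.21, 2.01 against 39.2 CPM), Lgals3 (-3.90 ± 0.29), S100a6 (-3.76 ± 0.28), Aldh1a3 (-3.72 ± 0.40) and Col6a1 (-3.07 ± 0.24). Of 25 ribosome biogenesis genes and MYC targets 24 were lower, as were 14 of 15 unfolded protein response genes. Of 21 integrated stress response genes 17 were lower and 1 higher, including Trib3 (-1.88), Asns (-0.77), Slc7a11 (-0.71) and Atf4 (-0.56) (all 3 lists: adjusted p = 0.124 with an estimated correlation). Quiescent stem cell and astrocyte markers were higher in 16 of 23 cases and lower in 2 (adjusted p = 0.0592 with an estimated correlation). Pou5f1 lay at 0.620 ± 0.180 CPM (3.86 times, exact p = 0.0286), Sox2 at 224, Klf4 at 7.72 and Myc at 144 CPM.

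During differentiation of old cells doxycycline raised the nucleotide receptor gene P2ry2 (ENSMUSG00000032860, chromosome 7, 100996568 to 101012866) at every time. It went from 7.54 ± 0.887 to 12.7 ± 0.817 CPM at 6 h (0.75 ± 0.08, adjusted p = 0.00716) and from 24.2 ± 1.55 to 35.0 ± 2.05 CPM at 18 h (0.52 ± 0.05, adjusted p = 0.00299). By 48 h it had gone from 9.82 ± 1.31 to 17.4 ± 1.73 CPM (0.81 ± 0.10, adjusted p = 0.0113; n = 4 and 4 each). Agpat4 rose by 0.64 ± 0.05 at 6 h (adjusted p = 6.79e-04) and 0.46 ± 0.05 at 18 h (adjusted p = 0.00802), and with animals as blocks by 0.33 at 48 h. At 6 h Slc29a3 (0.33 ± 0.03, adjusted p = 0.00533), the scaffold gene Ppp1r9b (0.28 ± 0.03, adjusted p = 0.0108) and mt-Nd3 (0.74 ± 0.07, adjusted p = 0.0110) also rose. At 48 h mt-Nd2 rose from 1738 ± 135 to 2706 ± 194 CPM (0.63 ± 0.07, adjusted p = 0.00833) and Glycam1 fell by 0.95 ± 0.12 (3.72 ± 0.465 against 7.11 ± 1.08 CPM, adjusted p = 0.0113). Filip1l (0.90) and 1700025G04Rik (0.46) complete the calls at 48 h and are named after their values were seen. In all 5 genes changed at 6 h, 2 at 18 h and 5 at 48 h. Blocked fits called 288 up and 337 down, 83 up and 67 down, and 360 up and 341 down. Leaving out 1 animal gave 130 to 445, 21 to 250 and 166 to 1101 genes in these fits. Sox2 was at 323 against 336, 312 against 329 and 277 against 291 CPM at the 3 times.

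Oligodendrocyte lineage markers rose with doxycycline in the blocked fits at each time of differentiation, in 6 of 20, 9 of 22 and 11 of 23 tested members, with none lower (7, 14 and 15 adjusted over the list alone). The list had an adjusted p = 0.346 with an estimated correlation at 6 h, then 0.482 and 0.0775. With the share of counts on features overlapping ribosomal RNA as a covariate 6, 1 and 12 members passed, and the median at 18 h was 0.18 against 0.16 without it. The matrix gene Tnr rose by 0.41, 0.34 and 0.35. The choline phosphodiesterase gene Enpp6, a mark of newly forming oligodendrocytes, rose by 0.59, 0.56 and 0.26. Gpr17 rose by 0.31, 0.29 and 0.26. At 48 h 14 of 22 cholesterol synthesis genes rose, among them Nsdhl (0.30), Dhcr7 (0.28), Lss (0.24) and Cyp51 (0.22) (adjusted p = 0.138 with an estimated correlation; 21 adjusted over the list alone). Of 23 quiescent stem cell and astrocyte markers 11 fell and 1 rose (18 and 1 adjusted over the list alone), the falls including Ntsr2 (-0.27), Slc1a2 (-0.27), Gja1 (-0.24) and Aqp4 (-0.23) (adjusted p = 0.0775 with an estimated correlation). Single genes of the blocked fits were mt-Atp6 (0.40), Gal3st1 (0.41), Kcnn2 (-0.39) and Masp2 (-0.41) at 6 h. At 18 h they were Scg2 (0.46), Elfn2 (0.41), Cftr (-0.41) and the complement gene C4b (-0.49). Those at 48 h were Stum (0.48), Gng4 (0.44), Scn3a (0.43), Rab33a (0.42), Plagl1 (-0.65), Rnase1 (-0.61), Gadd45b (-0.60), Osmr (-0.55) and Thrsp (-0.50). At 18 h the share of counts on features overlapping ribosomal RNA was 1.83 ± 0.210% with doxycycline and 2.47 ± 0.353% without it (exact p = 0.0571, adjusted 0.162). With this share as a covariate the blocked fit called 5 genes.

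**Figure D2:**
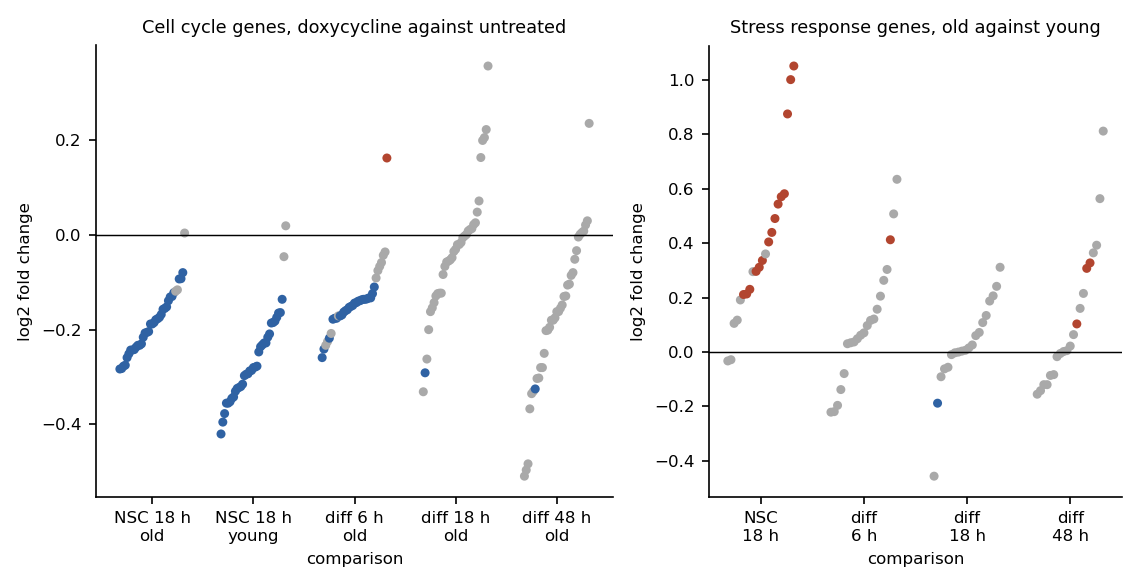
Left, log2 fold changes of cell cycle genes with doxycycline in the 5 matched comparisons, coloured where the gene passed with animals as blocks (34 lower in old cells at 18 h). Right, log2 fold changes of integrated stress response genes between old and young cells in the 4 comparisons of age, coloured where the gene passed (15 in stem cell medium).

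By calls of single genes, young cells in differentiation medium had lower ribosome biogenesis genes and MYC targets than cells in stem cell medium at 18 h. Most glial markers were higher. As lists these mostly did not pass with an estimated correlation. Medium is joined here with time in culture, and in stem cell medium old cells with doxycycline differed in 10222 genes between 6 and 18 h and 8814 between 48 and 18 h. At 6 h 6512 genes rose and 6183 fell (74.9% of tested genes), at 18 h 7188 and 6845 (82.6%) and at 48 h 7111 and 6984 (83.0%). Gpr17 rose from 1.47 to 385 CPM at 18 h (8.07 ± 0.39, n = 5 and 5) and 1403 CPM at 48 h (9.93 ± 0.41). Ndrg2, a gene of differentiating astrocytes, rose from 5.80 to 216 CPM at 6 h (5.24 ± 0.29) and 1231 CPM at 18 h (7.77 ± 0.30), and Wnt4 rose from 0.302 to 17.3 CPM at 6 h (5.90 ± 0.28). The retinoic acid hydroxylase gene Cyp26b1 (5.6 ± 0.15), Cd82 (5.22), Mmd2 (5.21) and Actc1 (4.85) followed at 6 h. Bmp3 (8.30), Neu4 (8.07) and Rnase1 (8.07) did so at 18 h, and the fatty acid hydroxylase gene Fa2h (9.72), Lgi4 (9.72), Fxyd3 (9.56) and Fxyd1 (9.46) at 48 h. Arc, an immediate early gene, fell from 111 to 1.37 CPM by 6 h (-6.31 ± 0.09), the peptide gene Apln from 584 to 11.6 CPM (-5.62 ± 0.29). Tnfsf18 (-6.15), Prokr1 (-5.26), Hmga2 (-4.71) and Rasl11a (-4.41) fell with them. By 48 h the largest falls were in Adamts14 (-8.13), Aldh1a3 (-7.99), Cd93 (-7.62), Htr1b (-7.54), Arc (-7.51) and the osteopontin gene Spp1 (-7.47).

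Ribosome biogenesis genes and MYC targets fell while most oligodendrocyte and astrocyte markers rose. All 25 ribosome biogenesis genes and MYC targets fell at each time (medians -1.78, -1.71 and -1.13). Their list had an adjusted p = 0.134 with an estimated correlation, then 0.0412 and 0.183, the second being 0.146 with animals as blocks. Rrs1 was at -2.38 at 6 h, Srm at -2.45 and Nop58 at -2.13 at 18 h, and Fbl at -1.61 at 48 h. Of 37 cell cycle genes 22 rose and 13 fell at 6 h. All 37 fell at 18 h (median -4.29, adjusted p = 0.304 with an estimated correlation) and 48 h (median -4.52, adjusted p = 0.183 with an estimated correlation). Cyclin D1, encoded by Ccnd1, went from 3491 to 53.5 CPM at 18 h (-5.98 ± 0.16) and 32.2 CPM at 48 h (-6.72 ± 0.13), and the replication genes Mcm3 (-4.11) and Mcm2 (-3.29) fell at 18 h. Oligodendrocyte markers rose in 17 of 20, 18 of 21 and 19 of 23 tested members with 1 lower at each time (adjusted p = 0.271 with an estimated correlation, then 0.364 and 0.484). They include Tnr at 48 h (5.52, 1073 against 24.1 CPM) and the precursor receptor gene Pdgfra (2.47, 4.72 and 4.76). Astrocyte and quiescence markers rose in 19 of 23, 22 of 24 and 21 of 24 members (adjusted p = 0.616 with an estimated correlation, then 0.304 and 0.115). They include Cst3 (2.14, 3.89 and 4.76, 5475 against 208 CPM at 48 h), Glul (1.28, 2.35 and 3.47) and S100b (3.03 and 4.53 at 6 and 18 h). Feedback genes of growth factor signalling fell in 16, 16 and 17 of 20 cases, with Dusp4 at -3.86 at 6 h, Spry4 at -3.96 at 18 h and Spry1 at -3.74 at 48 h (adjusted p = 0.336 with an estimated correlation, then 0.329 and 0.183). Cholesterol synthesis genes fell in 20, 22 and 20 of 22 cases, such as Hsd17b7 (-2.07, -1.97 and -1.36) (adjusted p = 0.616 with an estimated correlation, then 0.427 and 0.653).

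**Figure D3:**
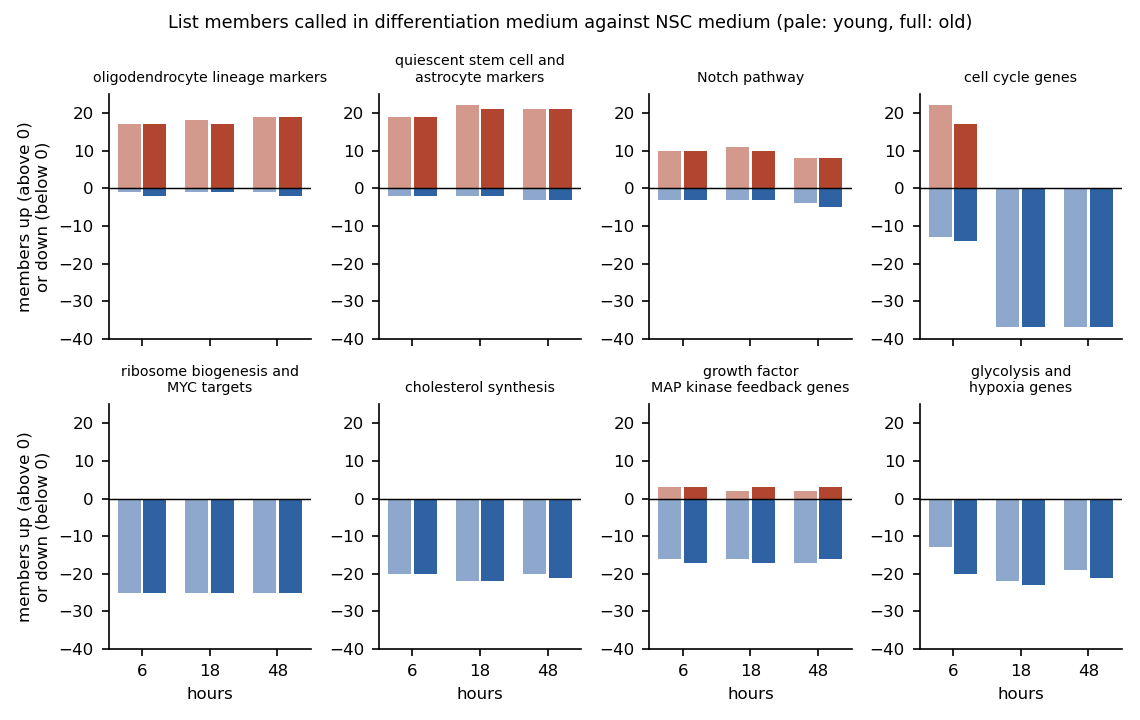
Number of list members higher and lower in differentiation than in stem cell medium at 6, 18 and 48 h, in young (pale) and old (full) cells, for 8 gene lists. All 37 cell cycle genes are lower at 18 and 48 h in both ages.

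In old cells 6476 genes rose and 6346 fell at 6 h, 7054 and 6896 at 18 h, and 7141 and 6898 at 48 h (n = 4 and 4). Gpr17 went from 3.08 to 714 CPM at 18 h (7.89 ± 0.36) and 2571 CPM at 48 h (9.76 ± 0.36). The lipoprotein gene Apoe went from 13.4 to 4499 CPM at 18 h (8.43 ± 0.38). By 48 h Enpp6 went from 0.410 to 242 CPM (9.26 ± 0.30). At 6 h Fbp1 (5.66), Wnt4 (5.54), Ndrg2 (5.38), Cyp26b1 (5.28), Cd82 (5.26) and Mmd2 (5.04) rose most. Tnfsf18 (-6.73), Prokr1 (-6.37), Arc (-6.24), Apln (-6.10 ± 0.11, 6.95 against 485 CPM), Hmga2 (-4.76) and Egr3 (-4.71) fell most. At 18 h Slc30a10 (8.25) and Rnase1 (7.80) rose, and Adamts14 (-7.25), Cd93 (-6.97), Spp1 (-6.78), Cdc6 (-6.59) and Depdc1a (-6.57) fell. At 48 h the myelin gene Mag rose by 9.26 and the myelin regulator Myrf by 5.58, while Liph (-8.04), Aldh1a3 (-7.92) and Adamts14 (-7.79) fell. The 37 cell cycle genes fell with medians of -4.83 at 18 h and -4.94 at 48 h (adjusted p = 0.136 with an estimated correlation, then 0.182). The 25 ribosome biogenesis genes and MYC targets all fell at each time (adjusted p = 0.104 with an estimated correlation, then 0.136 and 0.33).

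Age changed 994 genes in untreated stem cell medium at 18 h, 516 higher and 478 lower in old cells. Leaving out 1 library gave 405 to 1544 genes. Chac1 (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381), a glutathione-degrading target of the integrated stress response, lay at 10.1 ± 1.05 CPM in old and 5.00 ± 0.544 CPM in young cells (1.0 ± 0.10, n = 4 and 5). The RNA-binding protein gene Igf2bp2 (ENSMUSG00000033581, chromosome 16, 22059009 to 22163299), which supports fetal and adult progenitor growth, lay at 11.3 ± 2.43 against 32.5 ± 7.54 CPM. The progenitor transcription factor Gsx1 (1.12 ± 0.24, 8.04 against 3.67 CPM), the stress pseudokinase gene Trib3 (1.05 ± 0.18, 7.85 against 3.76 CPM), the phosphatase subunit gene Ppp2r2c (1.02 ± 0.16, 27.1 against 13.3 CPM) and Cyb5r2 (1.02 ± 0.13) were higher. The focal adhesion gene Tgfb1i1 (-1.76 ± 0.34, 4.87 against 16.4 CPM), Anxa3 (-1.35 ± 0.19) and Hlx (-1.15 ± 0.17) were lower. Nrn1 (-1.10 ± 0.26) and Fkbp10 (-1.05 ± 0.24) were lower too, with adjusted p = 0.0655 and 0.0536 once sex was a covariate. Integrated stress response genes were higher in old cells in 15 of 22 cases (17 adjusted over the list alone; camera adjusted p = 3.09e-26, adjusted p = 0.0114 with an estimated correlation). They include the amino acid transporter gene Slc7a5 (0.57 ± 0.06, 290 against 194 CPM), the asparagine synthetase gene Asns (0.40 ± 0.05, 134 against 100 CPM) and the regulator Atf4 (0.30 ± 0.03, 210 against 169 CPM). Ddit3 is counted as 2 features that share its symbol, both higher (0.58 and 0.54). Matrix and adhesion genes were lower in 9 of 32 cases (11 adjusted over the list alone, with 1 higher; adjusted p = 0.18 with an estimated correlation), among them Lama2 (-0.72), Itgb5 (-0.45), Lamb1 (-0.35) and Itgav (-0.25). Of 22 cholesterol synthesis genes 5 were higher (9 adjusted over the list alone), such as Fdft1 (0.39) (adjusted p = 0.686 with an estimated correlation). The senescence gene Cdkn2a was lower in old cells (-0.37). The ribosomal RNA share was 0.981% in old and 1.49 ± 0.148% in young libraries (exact p = 0.0397, adjusted 0.135), and with this share as a covariate 26 genes passed.

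In differentiation medium age changed 246 genes at 6 h, 880 at 18 h and 1815 at 48 h (n = 4 and 5). With the ribosomal RNA share as a covariate the counts were 487, 170 and 1819, and without old replicate 3 they were 72, 290 and 572. The cell cycle inhibitor gene Cdkn1c (ENSMUSG00000037664, chromosome 7, 143458339 to 143461050) was higher in old cells at 6 h (1.25 ± 0.20, 19.2 ± 4.05 against 8.05 ± 1.95 CPM), 18 h (1.04 ± 0.16) and 48 h (1.03 ± 0.17, 9.09 against 4.49 CPM). Igf2bp2 was lower at 6 h (-1.74 ± 0.25, 4.17 against 14.0 CPM) and 48 h (-1.49 ± 0.23), and the growth factor receptor adaptor gene Grb10 at 6 h (-1.15 ± 0.21) and 48 h (-1.42 ± 0.26). At 6 h Phactr3 (0.94 ± 0.10) and the protocadherin genes Pcdhb2 (0.89 ± 0.12), Pcdha4 (0.83), Pcdha9 (0.79) and Pcdha7 (0.77) were higher, and Npnt (-0.85), Ncs1 (-0.76) and Angpt2 (-0.72) lower. At 18 h Sema3d (1.05 ± 0.18), Dpp10 (1.03), C1ql1 (0.99), Fa2h (0.98) and Unc5c (0.98) were higher. Tgfb1i1 (-1.72), the KIT ligand gene Kitl (-1.07 ± 0.13), Grin2c (-0.89) and Zfp853 (-0.82) were lower. With sex as a covariate the adjusted p was 0.0572 for Grb10 at 6 h, and 0.0657 for Dpp10 and 0.0574 for Tgfb1i1 at 18 h. At 48 h Cbln2 (1.46 ± 0.25), Csmd3 (1.10 ± 0.15), Inava (0.97), Srpk3 (0.90) and the BMP target Id3 (0.89 ± 0.16, 55.2 against 30.1 CPM) were higher. Grin2b (-0.89), Adamts12 (-0.81) and the kinase gene Cdk6 (-0.80) were lower.

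By list, old cells at 18 h of differentiation had 13 of 22 cholesterol synthesis genes higher (18 adjusted over the list alone), such as Fdps (0.35), Lss (0.29) and Cyp51 (0.28). At this time 11 of 25 ribosome biogenesis genes and MYC targets were also higher (19 adjusted over the list alone, with 1 lower). Examples are Srm (0.32) and Rrs1 (0.28) (both lists: adjusted p = 0.253 with an estimated correlation). At 48 h 15 of 25 ribosome biogenesis genes and MYC targets were higher (22 adjusted over the list alone, with 1 lower). Their list had an adjusted p = 0.222 with an estimated correlation. Neuroblast and neuron markers were lower in 11 of 28 cases and higher in 3 (15 and 5 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation), led by the interneuron transcription factors Dlx1 (-1.63) and Dlx2 (-1.29) and the GABA synthesis gene Gad2 (-1.02). Activated progenitor markers were lower in 6 of 16 cases (with 2 higher adjusted over the list alone), including Egfr (-0.59), Sox1 (-0.38) and Hes6 (-0.27) (adjusted p = 0.198 with an estimated correlation). Cdkn2a stayed lower in old cells at 6 h (-0.44), 18 h (-0.34) and 48 h (-0.33).

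The change from stem cell medium to differentiation differed between the young and the old animals for 8 genes at 6 h, 145 at 18 h and 686 at 48 h. Leaving out 1 animal gave 0 to 9 at 6 h, 7 to 659 at 18 h and 118 to 1340 at 48 h. These counts therefore depend on single animals, and whether age underlies them stays open. Chac1 fell more in old cells, by 0.98 ± 0.16 at 6 h (adjusted p = 0.0164) and 1.48 ± 0.18 at 18 h. Slc7a5 changed by -0.83 in old and -0.35 in young cells at 6 h (interaction -0.48 ± 0.07). At 6 h the stress gene Gadd45b (-0.86 ± 0.15), G0s2 (-0.58), Jdp2 (-0.53), Ets1 (-0.48) and Erf (-0.44) had negative interactions and the kinase gene Hunk a positive one (0.61 ± 0.09). At 18 h Nell2 (-0.78 ± 0.08, adjusted p = 1.2e-04), Ubald2 (-0.52), Peli2 (-0.44), Gpc1 (-0.41), Nup62 (-0.37) and Nars (-0.34) were negative. Sorl1 (0.83 ± 0.14), Frem1 (0.71), Irs2 (0.41), Pan3 (0.36), Lrch3 (0.35) and Ercc6 (0.32) were positive. At 48 h Apcdd1 (-0.92 ± 0.13), Nell2 (-0.77 ± 0.10), Ubald2 (-0.58), Endod1 (-0.51), Akap7 (-0.48) and Sun2 (-0.46) were negative. Tmem255b (0.63), Slc22a17 (0.53), Pdxp (0.40), Lrch3 (0.37), Btbd3 (0.36) and Fyttd1 (0.31) were positive. Integrated stress response genes fell more in old cells in 2 of 22 cases at 6 h (9 adjusted over the list alone; adjusted p = 6.56e-04 with an estimated correlation). They did so in 6 of 21 at 18 h (11 adjusted over the list alone; adjusted p = 0.0111 with an estimated correlation) and 9 of 22 at 48 h (11 adjusted over the list alone, with 1 the other way; adjusted p = 0.0141 with an estimated correlation). With animals as blocks the lists at 18 and 48 h had adjusted p = 0.0558 and 0.141 with an estimated correlation. The interactions at 6, 18 and 48 h all use the same stem cell medium libraries at 18 h, in which most of these genes were already higher in old cells. The times are therefore not independent, and that starting difference alone can appear as a larger fall at each of them.

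Of the genes changed with age in stem cell medium, 65.9% had a doxycycline effect at 18 h with the sign toward the young level in old cells. This share counts signs. In the unblocked fit behind it 0 age genes were called in the opposite and 1 in the same direction. Simulations with no doxycycline effect, which keep the shared libraries, gave 61.9% (60.9 to 63.2%). They draw no shifts common to many genes of a library, so the gap to 65.9% cannot be read as an effect. Comparisons using different untreated animals gave 61.4% (53.6 to 68.9%). About 50% would be expected there without an effect, but only if the untreated old libraries have no state in common. Features overlapping ribosomal RNA held 0.981% of their counts, against 1.71% with doxycycline and 1.49% in untreated young cells. A value above 50% therefore does not separate doxycycline from such a state. All 6 splits lay above 50%, but they reuse the same animals and are not independent. With the share of counts on features overlapping ribosomal RNA as a covariate in the blocked doxycycline fit it was 60.8% of 989 genes. With that share in both fits only 26 age genes remained, too few to read a change from their 50%. The covariance of age and doxycycline effects was -0.0167, against -0.0083 in the simulations and -0.0071 with different animals. With animals as blocks 137 genes higher in old cells fell with doxycycline (36.4 expected from the sizes of the gene sets if the comparisons shared no library) and 57 lower in old cells rose (19.8 expected). In the same direction were 11 and 45 (21.6 and 33.4 expected). The 6 splits with different untreated animals, with age genes at an unadjusted p under 0.01, gave 62, 81, 90, 139, 2 and 35 genes in opposite and 18, 66, 48, 63, 0 and 36 in the same direction, so the excess varied with the animals. Examples from the blocked fit with their age and doxycycline effects are the oligodendrocyte regulator Nkx2-2 (0.63 and -0.19), Ubald2 (0.41 and -0.29), Slc7a5 (0.57 and -0.10), Snrpc (0.23 and -0.13) and Nup62 (0.27 and -0.11). Genes lower in old cells include Lamb1 (-0.35 and 0.16) and Sec61g (-0.20 and 0.16). Against untreated cells at 18 h, 43.4% of age genes lay toward young at 6 h (simulated 64.0%, different animals 42.1%) and 59.5% at 48 h (simulated 66.0%, different animals 55%). At 6 h 309 genes were called in opposite and 418 in the same direction, of which 250 were lower in both (146.4 expected if the comparisons shared no library). The counts at 48 h were 396 and 245. Genes in opposite directions include Ets1 (0.38 and -0.39), Nkx2-2 (0.63 and -0.70) and H1fx (0.50 and -0.50) at 6 h, and Atf4 (0.30 and -0.56) and Chac1 (1.0 and -1.25) at 48 h.

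In differentiation the doxycycline effect had the sign toward young for 52.7% of age genes at 6 h (simulated 62.6%, different animals 49.5%), 50.4% at 18 h (63.4% and 45.6%) and 31.9% at 48 h (64.7% and 25.7%). In the unblocked fits behind these shares 0, 0 and 2 age genes were called in the opposite and 0, 1 and 1 in the same direction. At 48 h the blocked fits shared 118 genes higher in old cells and raised by doxycycline (20.6 expected) and 72 lower in both (17.2 expected), against 6 and 10 in opposite directions (19.5 and 18.1 expected). The splits with different untreated animals gave 121, 2, 12, 329, 132 and 14 genes in the same and 3, 1, 2, 8, 8 and 1 in opposite directions. At 6 and 18 h the genes named here passed both tests in opposite directions with animals as blocks. At 6 h these were 12 genes, against 8 in the same direction, and include Cdkn1c (1.25 and -0.20), Parvb (0.31 and -0.31), Grb10 (-1.15 and 0.22) and Adamts9 (-0.42 and 0.24). At 18 h they were 6 genes, against 25 in the same direction of which 21 were higher in both (2.4 expected), and include Hpgd (0.95 and -0.31), Fdps (0.35 and -0.19), Hmgcs1 (0.35 and -0.16) and Galnt16 (-0.18 and 0.18). At 48 h Filip1l (-0.45 and 0.90) and mt-Nd2 (-0.22 and 0.63) moved toward young without blocks, and Tfrc (0.32 and -0.15) and Ifi27 (0.24 and -0.15) with animals as blocks.

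**Figure D4:**
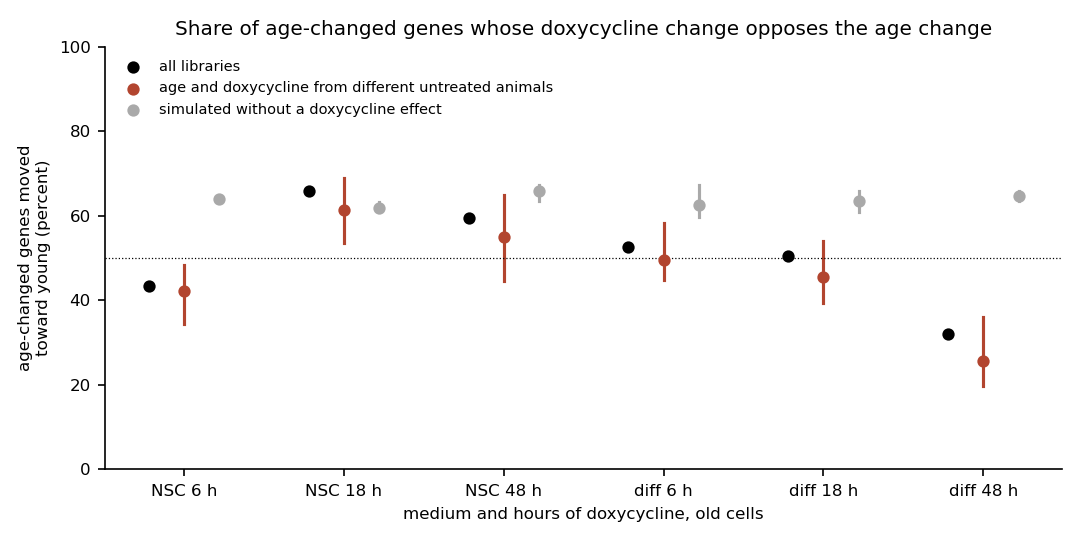
Percent of genes changed with age whose doxycycline effect, called or not, had the sign toward the young level. Shown are all libraries (black), different untreated animals in each comparison (red, mean and range of 6 splits) and simulations without a doxycycline effect (grey, mean and range of 5 runs). At 48 h of differentiation the share is 31.9% against 64.7% in the simulations. The splits share no untreated library. Without a doxycycline effect both directions would be equally likely there, unlike in the simulations, if the untreated old libraries have no state in common.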

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

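The explanations and the splits of the libraries in this part were chosen only after the results were seen, though the fit with sex as a covariate was planned.

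In 9 of 105 groups tested, 1 library lay apart from the others, and chance marks about 1 in 20 groups. Features overlapping ribosomal RNA held 3.54% of counts in old replicate 1 with doxycycline at 6 h in stem cell medium (others 0.389 to 0.597%), 0.271% in old replicate 2 with doxycycline at 48 h of differentiation (others 2.09 to 2.46%) and 1.98% in untreated young replicate 3 at 48 h of differentiation (others 2.67 to 2.79%). Total counts were 103.6 M in old replicate 2 with doxycycline at 48 h of differentiation (others 80.6 to 82.1 M) and 82.4 M in old replicate 1 with doxycycline at 6 h of differentiation (others 84.1 to 84.5 M). Among the factors in old cells with doxycycline, Pou5f1 was at 0.207 CPM in replicate 1 at 18 h in stem cell medium (others 0.464 to 0.479), Klf4 at 3.21 CPM in replicate 2 at 18 h of differentiation (others 2.34 to 2.45), and at 6 h of differentiation Myc at 17.4 CPM in replicate 4 (others 18.5) and Sox2 at 334 CPM in replicate 3 (others 318 to 320).

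The effect of differentiation differed between the ages, by the test of the difference itself, for 8 genes at 6 h, 145 at 18 h and 686 at 48 h. Of 126 splits of the animals 40 were drawn. The real split gave the most genes at 6 h (8, highest other split 0) but not at 18 h (145, highest other 499) or 48 h (686, highest other 805). The splits not drawn were not tried, so chance is not excluded at any of these times. At 6 h at most 1 gene stayed without old replicate 2, 3 or 4 or without young replicate 1. The splits above the real count point to a structure among the animals beyond age. The effect of doxycycline at 18 h differed between the ages for 589 genes with animals as blocks and for 0 genes without blocks (edgeR; 1516 genes with an unadjusted p under 0.05, and 3 genes by DESeq2).

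Of the features for transgene sequences, M2rtTA was abundant enough to enter the fits of all genes, and P2A, T2A and E2A were not. In matched comparisons M2rtTA with doxycycline was at 0.953 to 1.09 times its untreated level. At 6 and 48 h in stem cell medium it was at 172.7 and 177.5 CPM, against 228.9 CPM in untreated old cells at 18 h (exact p = 0.0286 each). These 2 differences join time with doxycycline. M2rtTA had at least 4982 counts in every library. E2A had at most 4 counts in 3 libraries, all with doxycycline. P2A had 2 counts in 1 library with doxycycline and T2A 2 counts in 1 untreated library.

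In blocked fits 34, 35 and 26 cell cycle genes were lower with doxycycline. These counts are of old cells at 18 h, young cells at 18 h and old cells at 6 h of differentiation. At each of 18 and 48 h of differentiation 1 member passed as lower, though the median at 48 h was -0.177 against -0.143 at 6 h. With the share of counts on features overlapping ribosomal RNA as a covariate 28, 35 and 21 members were lower, and after removal of trends with GC content and gene length 36, 35 and 26, which argues against either as the whole cause. An integrated stress response set off by doxycycline is argued against by its members, of which 0, 3 and 0 were higher. An effect of doxycycline itself, which may slow division without the factors, was not tested since the labels give no animals without the cassette, and an effect of the induced factors stays open as untested beside it.

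Integrated stress response genes were higher in old cells in stem cell medium in 15 of 22 cases. Ddit3 enters these counts once for each of the features sharing its symbol. With the ribosomal RNA share as a covariate the list kept its direction, with a median of 0.31 against 0.32 and an adjusted p = 0.00518 with an estimated correlation, although 4 members then passed on their own. A passing state of the untreated libraries is argued against by the libraries with doxycycline, where 18 of 21 members were higher in old cells, and sex by a fit with sex as a covariate, where 12 were higher. An effect of age may therefore underlie it as a hypothesis found in the same data. The animals are the same in both sets of libraries, so a difference between these 9 animals other than age stays open.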

How the results depend on the processing

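The settings with counts halved, with the ribosomal RNA share as a covariate, with GC content and length, with 18 h doxycycline libraries as the control, with blocks in the shares moved back, and those varying a blocked fit were chosen only after the results were seen. The rest were chosen before the data were examined.

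Over 1539 results for named genes 24240 of 25446 values kept their direction and their side of the threshold, 780 lost the call, 391 gained it, and 35 changed direction where the main fit made no call. These values do not cover the ribosomal RNA share, GC content and length or the 18 h doxycycline control, which were run for counts of genes, and 220 more values could not be tested under a setting. In the 6 comparisons of differentiation and the comparisons with doxycycline at 6 and 48 h in stem cell medium, no alternative moved a count by more than 1.5 times. RLE normalisation and halved counts moved no count, and the sex covariate moved no count of age comparisons. Without TMM the 28 factor ratios moved by less than their spread between libraries, while the exact p of Myc in old cells at 18 h went from 0.0286 to 0.0571. The cause was not tested for the changes below unless named.

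Genes changed with doxycycline are given in the order old and young cells at 18 h in stem cell medium, then old cells at 6, 18 and 48 h of differentiation (3, 6, 5, 2 and 5 genes). DESeq2 called 110, 213, 87, 41 and 87. With animals as blocks, paired as the labels pair them, 1863, 2260, 625, 150 and 701 genes were called, which removes the spread between animals. Blocking changed no other count of 2 groups by over 1.5 times. Without a filter the first 4 were 6, 10, 10 and 5, with the stricter filter the first 2 were 1 and 10, and with all groups in 1 fit they were 11 and 260 in stem cell medium and 6 and 2 at 18 and 48 h of differentiation. Limma on the deposited values gave 6 at 18 h of differentiation.

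In blocked fits, DESeq2 called 1159 genes in old cells at 18 h. The ribosomal RNA share as a covariate gave 731 there and 358 and 5 at 6 and 18 h of differentiation. Limma gave 295 at 6 h, and correction for GC content and length gave 973, 334 and 1258 at 6, 18 and 48 h. Leaving out 1 animal gave 1037 (replicate 2) to 1623 in old cells at 18 h, 1142 (replicate 2) to 3317 in young cells, 130 (replicate 1) to 445 at 6 h, 21 (replicate 1) to 250 (replicate 4) at 18 h and 166 (replicate 4) to 1101 (replicate 2) at 48 h. In unblocked fits leaving out 1 library gave 1 to 2 in old cells at 18 h, 4 to 713 in young cells (untreated replicate 5), 2 to 21 (untreated replicate 4) at 18 h and 1 to 5 at 48 h of differentiation.

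Age in stem cell medium (994 genes) gave 2020 with DESeq2, which gave 19.2% false calls on simulated data, 1663 with all groups in 1 fit, 26 with the ribosomal RNA share as a covariate, and 405 (old replicate 3 or young replicate 1) to 1544 (young replicate 5) without 1 library. At 6, 18 and 48 h of differentiation (246, 880 and 1815) DESeq2 gave 723, 1571 and 2748, the covariate 487 and 170 at 6 and 18 h, and all groups in 1 fit 664 at 6 h. Without 1 library the counts were 72 (old replicate 3) to 320, 290 (old replicate 3) to 1383 (old replicate 1), and 572 (old replicate 3) to 2461.

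The interaction of doxycycline and age gave 0 genes (edgeR; 1516 with an unadjusted p under 0.05), 3 with DESeq2, 589 with animals as blocks, and 0 to 75 (young replicate 5) without 1 animal. Interactions of differentiation and age at 6, 18 and 48 h gave 18, 561 and 1367 with DESeq2. With animals as blocks 29 were called at 6 h, and with sex and its interaction 4 and 81 at 6 and 18 h. Leave-one-out gave 0 (old replicates 3 and 4, young replicate 1) to 9, 7 (young replicate 1) to 659 (young replicate 5) and 118 (old replicate 3) to 1340 (young replicate 5).

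The share moved back toward young at 18 h in stem cell medium (65.9%) was 60.8% with blocks and the ribosomal RNA share in the doxycycline fit, 50% of the 26 age genes left with that share in both fits, and 59.2 to 71.3% without 1 animal. At 6 h it was 35.7 to 45.5% without 1 animal, and at 48 h 54.5 to 62.8%, with 55% where the untreated libraries were parted between the comparisons. In differentiation, age genes at an unadjusted p under 0.01 gave 61.2% at 6 h, and leave-one-out gave 37.5 to 53.9%, 41 to 63.6% and 21.4 to 31.9%. At 48 h parted untreated libraries gave 25.7%, blocks with the ribosomal RNA share 25.8% and that share in both fits 24.8%.

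Of 2480 list values 1849 kept their call, 419 lost it, 148 gained it and 64 moved, and of the losses 185 came with an estimated correlation and 149 with an estimated correlation and animals as blocks. Depth limits genes near the floor such as Pou5f1.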

Other observations

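The tests of a hypothesis and the splits of the libraries in this part were chosen only after the results were seen.

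Further lists moved as young cells differentiated. Interferon response genes were higher in 21 of 24 cases and lower in 1 at 6 h (adjusted p = 0.134 with an estimated correlation), with the antiviral genes Rsad2 (2.97) and Xaf1 (2.60) up, and at 48 h 13 were higher and 7 lower. Senescence and p53 targets were lower in 17 of 19 cases at 48 h (adjusted p = 0.0936 with an estimated correlation). Of the matrix and adhesion genes 23 of 32 were lower at 48 h, when 6984 of all 16991 tested genes were lower. The laminin gene Lama4 was at -1.42, -3.30 and -5.65 at 6, 18 and 48 h. The intermediate filament gene Nes, a stem cell marker, fell by 2.29 at 18 h and 3.38 at 48 h. The neuronal transcription factor gene Sox4 rose by 2.14, 2.13 and 1.73, and the inhibitor of neural differentiation Id3 fell by 0.77, 1.10 and 2.45.

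Col1a1 rose with doxycycline in blocked fits of old cells at 18 h (0.75, adjusted p = 0.0016), young cells at 18 h (0.46, adjusted p = 0.029) and old cells at 6 h of differentiation (1.05, adjusted p = 0.0022), at levels below 2 CPM. At 18 and 48 h of differentiation it did not pass (0.32 and 0.85, adjusted p = 0.513 and 0.186), and without blocks it passed in none of the 5 (adjusted p = 0.0746 to 0.788). A candidate explanation is a doxycycline-driven cassette inserted near Col1a1 that raises its neighbours. The test averaged the doxycycline effects of genes within 250 kb of Col1a1 (chromosome 11, 94936224 to 94953042) and set them against other windows of at least 4 genes: the mean was 0.18, and 0.00932% of 10731 other windows had one as high. Of its 4 neighbours in the window, Ppp1r9b and Samd14 were higher in all 5 matched comparisons and Pdk2 and Itga3 in 4, with Pdk2 at -0.02 in old cells at 18 h and Itga3 at -0.05 at 18 h of differentiation. Of all genes 7.91% were higher in all 5. The hypothesis was formed on the same data, and the labels do not give the insertion site.

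For differentiation, and for doxycycline at 6 and 48 h in stem cell medium, 1 of the tried splits of the libraries, the real one, gave as many genes. In old cells all 35 splits were tried, which argues against a chance division of the libraries there. These splits set the pairing by animal aside. In young cells 40 of 126 were drawn and the others were not tried, so chance is not excluded for them. The highest other counts were 9 and 12 for doxycycline at 6 and 48 h (real 10189 and 8825). They were at most 9 for differentiation (real 12695 to 14095). For age 40 of 126 splits were drawn, and no other drawn split gave as many genes. The counts were 994 in stem cell medium (highest other 13), and 246, 880 and 1815 at 6, 18 and 48 h of differentiation (highest others 2, 188 and 1173). The splits not drawn were not tried, so chance is not excluded for age. For matched doxycycline without blocks chance cannot be excluded: 4 of 35 splits gave as many genes in old cells at 18 h (3 genes, highest other 1042), 3 of 40 in young cells (6, highest other 1449), and 4, 5 and 2 of 35 at 6, 18 and 48 h of differentiation (5, 2 and 5, highest others 462, 71 and 218). Splits calling many more genes point to a structure of the samples: they keep both libraries of at least 2 animals on the same side, and among splits that part as many animals the highest count was 0. The interaction of doxycycline with age gave 0 genes in all 40 splits (edgeR; 1516 genes at an unadjusted p under 0.05, DESeq2 3 genes). Blocked fits have too few splits for a share under 0.05: the real counts were 1863, 2260, 625, 150 and 701 and the highest others 7, 56, 3, 0 and 0, and at 6 and 48 h in stem cell medium 11405 and 9648 against 0.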
